A study of Bos taurus with 36 samples.

How the data were processed

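The study profiled bovine oocytes on 2-colour microarrays, with 36 arrays from 3 Holstein cows. Per the labels' protocols, the cows received FSH for 3 days at 12 h intervals and went through the coasting times of 20, 44, 68 and 92 h in random order, a month or more apart. Oocytes were collected by transvaginal puncture and freed of cumulus cells mechanically, RNA was extracted with the PicoPure kit, amplified with RiboAmp HS and labelled with Cy3 or Cy5 by the ULS method. Each of the 12 extracts, 1 per cow and coasting time, is on 6 arrays, 3 per dye, and each of the 18 pairs of extracts within a cow is on 2 arrays with the dyes swapped. The cow is the replicate (n = 3), and arrays of the same extract are technical. The arrays sit on 9 slides of 4, each slide holds all 3 cows, and each pair of extracts was run on 1 of 3 days, per the deposited scanner files. For the pairs 20 and 44 h, 20 and 92 h, and 44 and 68 h, the dye orientations sat on different slides, the same in all 3 cows. A dye effect that differs between slides would enter these pairs alike in the 3 cows, and the spread between cows does not measure it.

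The deposited scanner files hold the mean and median intensity of each spot and its median local background in both channels as scanned, without background correction or normalization, per the file headers. The deposited series matrix holds log2 ratios of Cy5 over Cy3, and how the authors made these is not stated in the sources used here. The medians of its columns lay between -0.011 and 0.011, 869 values were missing, and its scale, centring and direction were checked against the scanner files, with a correlation over probes per array of 0.927 at the lowest and 0.973 at the median. No pair of arrays had identical files (0), and 0 per-sample columns were left out. An array has 45220 spots, of which 43794 are probes and 1426 are control or blank spots, 153 of them negative controls. In the table that pairs probes with genes, 21790 probes have 1 symbol, 0 have several and 22004 have none, and symbols are given as in that table.

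Starting from the mean spot intensities, the local background was corrected with normexp (offset 50), log ratios were normalized by loess within each array with control spots given next to no weight, and 117 spots marked in the scanner files were set to missing. For each probe and cow, least squares on the cow's 12 log ratios, with an intercept for the dye, gave the log2 level of each extract relative to the mean of the cow's 4 extracts. A probe was tested where its intensity passed the 95th percentile of the negative controls in 3 or more of the 6 channel measurements of an extract, in all 3 cows of at least 1 coasting time. This left 31712 probes and set 12082 aside, and signal near background limits what can be seen for dim probes. Dye-swapped arrays of the same pair should have opposite log ratios, and 14 of 18 correlated negatively over probes (median -0.317, from -0.811 to 0.118). For the pair of 44 h and 68 h the correlation was -0.139 in cow 2719, 0.0596 in cow 2959 and -0.777 in cow 2966.

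Coasting times were compared with limma on the 12 extract values, with the cow as a block and 6 residual and 1.64 prior degrees of freedom, for the 6 pairs of times, for 44 and 68 h against 20 and 92 h, and with an F test over the 4 times. The p-values were adjusted by the Benjamini-Hochberg method over all tested probes with a threshold of 0.05. The pairing comes from the labels, where the 4 extracts of a number are from the same cow. As a check on the separate channel values per extract, which keep differences between cows, deviations from the time means over probes correlated at a median of 0.292 for the 18 pairs from the same cow (from -0.649 to 0.664) and -0.189 for 36 pairs of different cow and time. Such deviations cancel out over the cows of a coasting time. The value for different cows is therefore tied to that for the same cow and is not an independent reference. Lists of genes were tested with camera at a preset correlation of 0.01, with the brightest tested probe for each of 12075 genes, adjusted over 17 lists and 7 contrasts (119 tests), and again with an estimated correlation. The lists were oocyte-specific genes, cumulus and granulosa markers, theca and stroma markers, blood cell markers, meiotic cell cycle, maternal mRNA storage and decay, chromatin and histones, apoptosis and stress, antioxidant enzymes, cAMP and meiotic arrest, lipid and sterol metabolism, DNA repair and damage response, qPCR reference genes, ribosomal proteins, oxidative phosphorylation, proteasome and mRNA splicing. Members were also counted past 0.05 adjusted over all probes and adjusted over the list alone. The adjustment over the list alone was made within each list and contrast and does not correct across the 119 of them. Some members that pass on it alone are therefore likely to be false calls.

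The lists, the tests, the rule for naming genes and most alternatives were set before the data were examined, while the percentile of the negative controls was chosen once the files showed no detection calls. Per contrast the text names up to 12 higher and 12 lower genes with the largest log2 change among those that passed with the same sign in 3 cows, or 6 and 6 for 68 h against 20 h and 92 h against 44 h. With fewer than 10 passing genes it adds those with the smallest p up to 10 as values. For the F test it names 10 by p, and for a list up to 4 members by p. A gene with several tested probes is named by the brightest that passed.

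Alternatives tried were no background correction, median centring, separate channels after Aquantile normalization with and without the cow as a block, no filter, the authors' log ratios, only the arrays that hybridised the 2 times directly, a dye intercept per slide, the array as replicate, an intensity trend with robust variance, and leaving out 1 cow at a time. After the data were seen, 2 extracts were left out singly and together, the DCP control spots and a residual component were used as covariates, and median spot intensities and brighter probes were tried. The fit was tested on simulated data with known changes, for 31712 simulated probes with the spread of the real ones. For 68 h against 44 h it recovered 14.9%, 61.2% and 84.8% of probes changed by 0.5, 1 and 2 log2 units and called 6 unchanged probes, and for 68 h against 20 h 13.4%, 56.7% and 83.3% with 7 unchanged. In 2 simulated comparisons without change it called 0 probes, and of 17 lists it found the shifted one and 0 others. The simulated probes varied independently of each other, while the first principal component of the real extracts held 71.7% of the variance. The simulation therefore does not show how the fit or camera behave on correlated probes. The work used R 4.3.3, limma 3.58.1, statmod 1.5.0 and data.table version 1.17.8.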

Results

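Gene expression was measured in oocytes of 3 Holstein cows on a bovine 2-colour microarray. Each cow received follicle-stimulating hormone (FSH, the pituitary hormone that drives follicle growth) for 3 days and was then left without it for a coasting period of 20, 44, 68 or 92 h before the oocytes were collected. The title of the series speaks of oocytes with high developmental competence, and the design asks how the oocyte's transcripts differ with the length of coasting. Every cow went through all 4 coasting times, which gave 12 RNA extracts. Each of the 6 pairs of extracts within a cow was hybridised in both dye orientations, for 36 arrays. The median spot intensity per array ranged from 125 to 538 in the Cy5 channel and from 187 to 509 in the Cy3 channel, against medians of 95.7 to 427 for the negative control spots. Of 43794 probes, 31712 were above background in all 3 cows at 1 or more coasting times and were tested, and 16456 of these carry the symbol of 1 of 12075 genes. Values are log2 differences between coasting times, given as the mean ± SD of the 3 cows (n = 3), and adjusted p-values come from limma with the cow as a block. The number of cows and arrays limits the precision.

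With all 12 extracts in the fit, most of the probes that passed did so at 68 h against 44 h of coasting. Without cow 2966 that count was 0 and 92 h against 68 h had 5486, and without both of the extracts that stood apart (described below) and all their arrays it was 0, with 2850 for 68 h against 20 h and 1280 for 92 h against 68 h. With both left out but the other extracts' values still taken from all arrays, 68 h against 44 h had 89 higher and 505 lower. In that fit 2503 passed for 68 h against 20 h and 144 for 92 h against 68 h. Several transcripts made by the oocyte itself were lower at 68 h. MOS, the kinase that keeps mature oocytes arrested in meiosis, fell 2.28-fold (-1.19 ± 0.37 on the log2 scale, adjusted p = 0.0391, lower in 3 of 3 cows). ZP2, a glycoprotein of the zona pellucida, fell 1.77-fold (-0.83 ± 0.24, adjusted p = 0.0492), and BCAR4, an oocyte transcript of cattle, fell 1.33-fold (-0.42 ± 0.094, adjusted p = 0.0367). INHBB, the beta B subunit of inhibin and activin, fell 1.86-fold (-0.90 ± 0.16), and SMAD6, an inhibitor of bone morphogenetic protein signalling, fell 1.85-fold (-0.88 ± 0.22). Among the transcripts that rose at 68 h were MARCH7, a ubiquitin ligase, by 1.92-fold (0.94 ± 0.080, adjusted p = 0.0349), and CDKN1B, the cyclin-dependent kinase inhibitor p27, by 1.57-fold (0.65 ± 0.15, adjusted p = 0.0464). In total 73 probes rose and 459 fell at an adjusted p of 0.05, all with the same sign in the 3 cows. They stand for 45 named genes that rose and 196 that fell, and the median size of the change was 0.51 log2 units. Of the called probes, 202 had a mean log2 intensity above 8.5, so most were dimmer. In a fit of such brighter probes alone, 0 of the 202 passed.

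The other genes named by rule that rose at 68 h over 44 h were the small GTPases ARL6 (0.74 ± 0.18), ARF4 (0.72 ± 0.10) and ARL15 (0.67 ± 0.17), the phosphatase PTP4A1 (0.86 ± 0.32), the zinc finger protein ZNF518A (0.77 ± 0.25), the DNA-binding protein FUBP3 (0.69 ± 0.12), IFRD1 (0.64 ± 0.068) and WDR47 (0.62 ± 0.21). Those that fell were COX6A1, a subunit of cytochrome c oxidase (-1.14 ± 0.52), MAD2L2, a subunit of the translesion DNA polymerase zeta (-1.04 ± 0.36), the chemokine receptor CXCR3 (-1.04 ± 0.36), the growth factor GDF11 (-1.01 ± 0.22), the alpha tubulin TUBA1D (-0.97 ± 0.16), the adhesion protein CTNND1 (-0.95 ± 0.26) and BIN3 (-1.01 ± 0.18). A further probe of MOS and of COX6A1 also fell. BIN3, MAD2L2 and CTNND1 each had a further probe that pointed the other way. Probes of TOX4 (0.81 ± 0.32), TM9SF2 (0.62 ± 0.18) and PNMA2 (-1.03 ± 0.44) passed while the other probes of these genes pointed the other way. A dim probe of RPL7, a ribosomal protein, fell (-0.93 ± 0.25), while the brighter probe of that gene stood at 0.35 ± 0.096 (adjusted p = 0.0613), so no direction is given for RPL7. CTNND1 was above background in 5 of its 18 channel measurements at 68 h and 13 of 18 at 44 h.

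Among gene lists drawn up before the data were examined, the oocyte-specific genes were lower at 68 h than at 44 h as a group. Of 39 members 26 had a negative change, their median was -0.25, and camera with a preset correlation gave an adjusted p = 0.00972, against an adjusted p = 0.683 with an estimated correlation. Adjusted over all probes 3 members fell and 0 rose, and adjusted over the list alone 10 fell, 0 rose and 29 did not pass, with ZP4 among the 10 (-0.78 ± 0.22). The adjustment over a list alone, here and below, does not correct across lists and contrasts. Ribosomal protein genes were also lower as a group (47 of 69 negative, median -0.20, adjusted p = 0.0292, and adjusted p = 0.683 with an estimated correlation). Their members went both ways, 3 higher and 5 lower adjusted over the list alone: RPL39 fell (-0.43 ± 0.092, adjusted p = 0.0391) and RPL21 rose (0.33 ± 0.019, adjusted p = 0.0412). Median centring in place of loess gave adjusted p of 0.0561 for the oocyte-specific and 0.107 for the ribosomal genes, leaving out cow 2719 gave 0.0865 and 0.0953, and a dye intercept per slide gave 0.067 for the ribosomal genes. On the arrays that carried both times directly, all run on the same day for a given pair, the medians were -0.31 and -0.19, and with the slide intercept -0.18 and -0.25. The direct arrays had the dye orientations on different slides, the same in all 3 cows. They therefore cannot part coasting time from a dye effect that differs between slides. In the 44 h extract of cow 2966, which stood apart from the other extracts, the median relative to the mean of the cow was 0.27 for the oocyte-specific and 0.18 for the ribosomal protein genes.

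No other list differed as a group between 68 h and 44 h, but several held members that changed. Adjusted over the list alone, the cumulus and granulosa markers had 1 higher and 4 lower of 28. INHBB, the steroidogenic regulator NR5A1 (-0.47 ± 0.15, adjusted p = 0.0434) and the activin-binding protein FST (-0.46 ± 0.15, adjusted p = 0.045) fell over all probes as well. The meiotic cell cycle list had 1 higher and 4 lower of 48, with PKMYT1, the inhibitory kinase of CDK1, lower (-0.48 ± 0.17, adjusted p = 0.0372) beside MOS, and CDKN1B higher. Among 47 genes of maternal mRNA storage and decay, 2 fell and 0 rose, the poly(A)-binding protein PABPC1L (-0.51 ± 0.17, adjusted p = 0.0365) and the mRNA-binding protein YBX1 (-0.69 ± 0.24, adjusted p = 0.0497). Of 80 oxidative phosphorylation genes 5 fell and 0 rose, and the cytochrome c oxidase subunits COX8B (-0.68 ± 0.085, adjusted p = 0.028) and COX6A1 passed over all probes too. Of 76 splicing genes 3 rose and 1 fell, with the splicing factors SFRS5 (0.40 ± 0.12, adjusted p = 0.0441) and SFRS6 (0.43 ± 0.17, adjusted p = 0.045) higher over all probes.

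Among 55 chromatin and histone genes 1 rose adjusted over the list alone, the remodeller SMARCA2 (0.55 ± 0.12), and 1 fell, SMARCB1 (-0.62 ± 0.23). Of 34 apoptosis and stress genes 1 rose, the caspase inhibitor XIAP (0.36 ± 0.023), and 1 fell, the BCL2 family member BCL2L11 (-0.39 ± 0.21). The lipid and sterol list had 1 lower member of 43, ACACA, the enzyme that makes malonyl-CoA (-0.39 ± 0.090). The qPCR reference list had 1 lower of 14, TUBA1A (-0.39 ± 0.070, adjusted p = 0.0717 over all probes). No member passed on either adjustment among 10 theca and stroma markers, 10 blood cell markers, 29 antioxidant enzymes, 26 cAMP and meiotic arrest genes, 46 DNA repair genes and 45 proteasome genes. The number of changed probes at 68 h against 44 h depended strongly on the fit. It was 0 without any of the 3 cows in turn and without the 92 h extract of cow 2719, 14 without the 44 h extract of cow 2966 and 0 without both extracts and all their arrays (left out after the data were seen), with 4147 to 6953 probes at an unadjusted p under 0.05 in these fits. The median size of the change of the called probes was 0.51, 0.54 and 0.47 without cow 2719, 2959 and 2966, 0.48 without the 44 h extract of cow 2966, 0.47 without the 92 h extract of cow 2719 and 0.42 without both, against 0.51 with all. With both extracts left out but the other values taken from all arrays, 292 of the called probes still passed, at a median of 0.48. The number was 4855 with a dye intercept per slide and 0 on the arrays that carried both times directly, within 1 day (5302 at an unadjusted p under 0.05). In separate channels after Aquantile normalization it was 0 (5412 at an unadjusted p under 0.05), and with median centring 12 rose and 480 fell. Of the called probes 204 were among those that passed with median centring. The called probes, which were chosen from the same data, kept their sign in each of these fits.

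**Figure D1:**
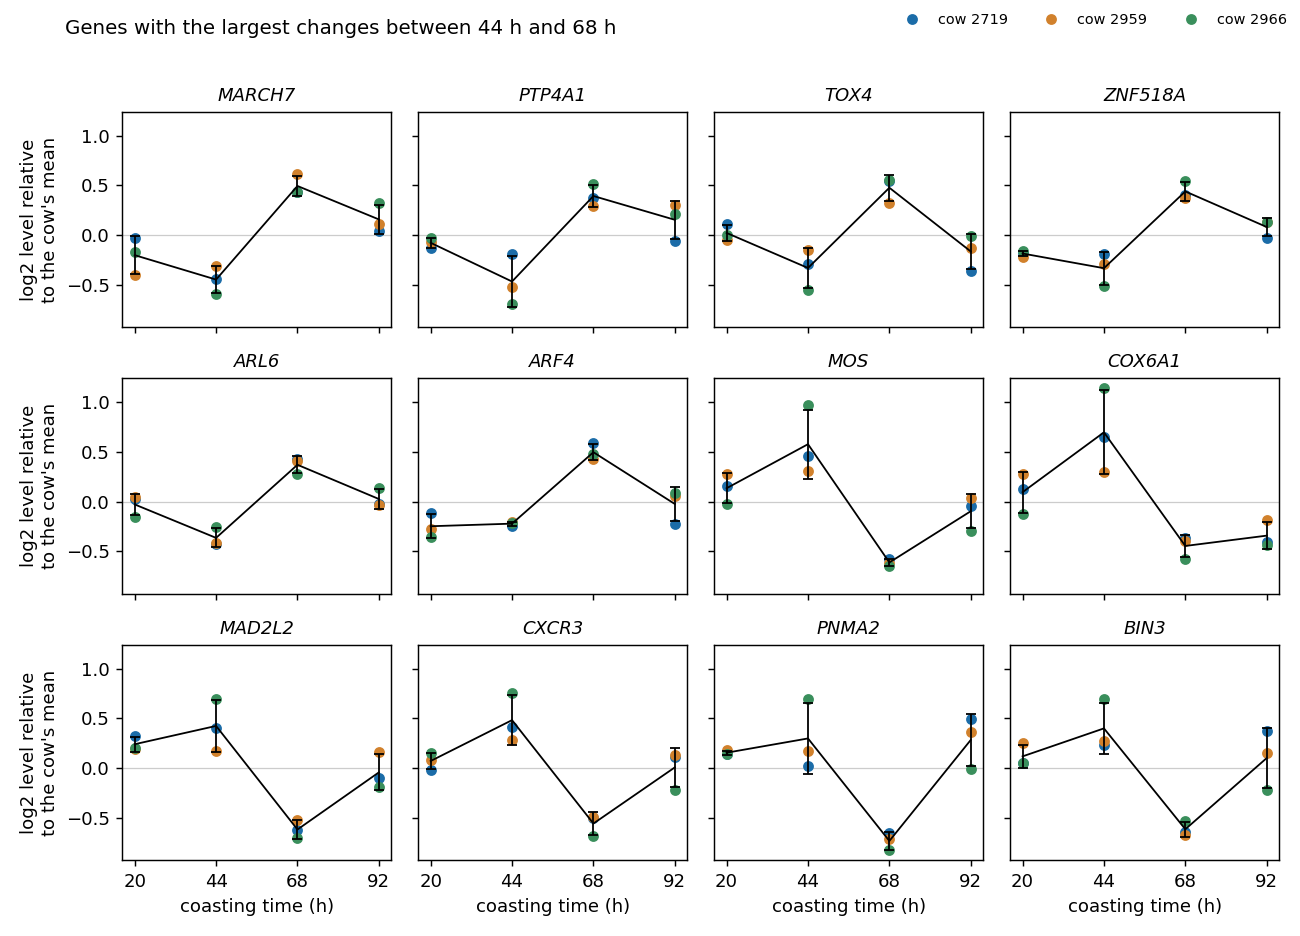
Log2 level relative to the mean of the cow (vertical axis) against coasting time in hours (horizontal axis) for the 6 genes with the largest rise and the 6 with the largest fall from 44 h to 68 h by the naming rule. Of these, TOX4, PNMA2, BIN3 and MAD2L2 each have a further probe that points the other way. Points are cows, black lines join the means and bars show the SD of 3 cows, and MOS fell by 1.19 and MARCH7 rose by 0.94 from 44 h to 68 h, a comparison that held 0 passing probes without any 1 cow.

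Against 20 h, oocytes after 68 h of coasting had less TUBA1D by 1.76-fold (-0.82 ± 0.10, adjusted p = 0.0402), less CLUL1, a relative of clusterin, by 1.75-fold (-0.81 ± 0.12, adjusted p = 0.0453), and less TPRG1L (-0.76 ± 0.023, adjusted p = 0.0402) and LYG2 (-0.65 ± 0.095, adjusted p = 0.0387), which was above background in 10 of 18 channel measurements at 68 h and 17 of 18 at 20 h. OOSP1, an oocyte-secreted protein, rose 1.44-fold (0.53 ± 0.035, adjusted p = 0.0488). A dim probe of PLAGL1, a zinc finger transcription factor, fell (-0.72 ± 0.064, adjusted p = 0.0333) and was above background in 6 of 18 channel measurements at 68 h and 18 of 18 at 20 h, while the brighter probe of PLAGL1 stood at 0.18 (adjusted p = 0.453). These 6 genes and 10 unnamed probes are the 16 that passed, 2 higher and 14 lower. DGAT2, the enzyme of the last step of triglyceride synthesis, stood 2.87-fold lower (-1.52 ± 0.087) but missed the threshold (adjusted p = 0.0543). MOBKL2A (-0.51 ± 0.13), ARL15 (0.78 ± 0.11) and LOC781001 (0.56 ± 0.066) had that same adjusted p.

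Splicing genes were higher at 68 h than at 20 h as a group (49 of 76 positive, median 0.15, adjusted p = 0.0292), with SFRS2 at 0.60 ± 0.20, PRPF3 at 0.77 ± 0.082 and HNRNPC at 0.53 ± 0.036. That call was lost with an estimated correlation (adjusted p = 0.982), with median centring (adjusted p = 0.107) and with no filter on dim probes (adjusted p = 0.0813). The median was 0.14 within the day of the pair and 0.14 with a slide intercept. Adjusted over the list alone, 1 splicing gene rose, SFRS2, and 2 of 43 lipid genes fell, DGAT2 (0.00194) and the lipogenic transcription factor SREBF1 (-0.57 ± 0.24). On the same adjustment OOSP1 rose and BCAR4 (-0.36 ± 0.12) and MOS (-0.75 ± 0.13) fell among the oocyte-specific genes. INHBB (-0.71 ± 0.17), FST (-0.44 ± 0.13) and NR5A1 (-0.40 ± 0.13) likewise fell among the cumulus and granulosa markers. XIAP (0.33 ± 0.10) and the brighter RPL7 probe (0.45 ± 0.11) rose. The count of 16 was 0 without any 1 cow, 560 without the 44 h extract of cow 2966, 5 without the 92 h extract of cow 2719 and 2850 without both (2503 with the other values from all arrays). The median size of the change of the 16 probes was 0.79, 0.75 and 0.75 without cow 2719, 2959 and 2966, against 0.78 with all, and 16 of 16 had the same sign. It was 2 with a slide intercept, 0 within the day of the pair (8514 at an unadjusted p under 0.05) and 1 higher and 74 lower with median centring. In separate channels it was 1 higher and 2 lower with the cow as a block and 0 higher and 2 lower without the block.

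Between 20 h and 44 h the oocyte-specific genes were higher at 44 h as a group, and 27 of 39 were positive. Their median was 0.13 (adjusted p = 0.0187, and adjusted p = 0.683 with an estimated correlation). ZP3 stood at 0.68 ± 0.67 and ZP2 at 0.39 ± 0.27, neither of them past the test. Ribosomal protein genes were higher as a group as well (48 of 69 positive, median 0.11, adjusted p = 0.0187, and adjusted p = 0.683 with an estimated correlation), with list medians from -0.066 to 0.12 in cow 2719, from 0.0066 to 0.18 in cow 2966 and from 0.084 down to 0.057 in cow 2959. No single probe passed in limma's test, with 2148 at an unadjusted p under 0.05. OOSP1 had the smallest p, at 0.67 ± 0.079 (adjusted p = 0.136, higher in 3 of 3 cows), and its brighter probe (0.55 ± 0.081) passed adjusted over the oocyte-specific list alone (0.000556). In the splicing list 2 rose and 3 fell on that adjustment, among them SFRS2 (0.56 ± 0.11), the U1 component SNRPC (0.51 ± 0.29), SFRS1 (-0.43 ± 0.13) and SFRS5 (-0.31 ± 0.12). The next genes by p were CTBP2 (-0.59 ± 0.10), EIF5 (-0.55 ± 0.13), SIK3 (0.36 ± 0.047), PIGM (-0.42 ± 0.042), TMED7 (-0.41 ± 0.11), QPCT (-0.41 ± 0.18), FAM175B (0.34 ± 0.13), C9H6ORF203 (-0.55 ± 0.21) and WDR47 (-0.58 ± 0.17), with adjusted p between 0.390 and 0.656. CTBP2, PIGM, FAM175B and C9H6ORF203 each had a further probe that pointed the other way. The oocyte-specific call ended without cow 2959 (adjusted p = 0.0666), without cow 2966 (0.122), without both of the extracts above (0.0755, or 0.0503 with the other values from all arrays), with median centring (0.161) and in separate channels (0.0508 with the cow as a block). The call of the ribosomal proteins ended without cow 2719 (0.182), without both extracts (0.0762, or 0.0503 with the other values from all arrays) and with median centring (0.716). The medians of these lists were 0.023 and 0.095 within the day of the pair and 0.13 and 0.14 with a slide intercept.

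From 68 h to 92 h a single probe without a gene symbol passed, 2.13-fold higher at 92 h (1.09 ± 0.12, adjusted p = 0.0434), with 4644 probes at an unadjusted p under 0.05. This probe was chosen by its values. Among named genes, CLUL1 (0.82 ± 0.14), SMAD6 (0.93 ± 0.10) and the dim probes of PLAGL1 (0.68 ± 0.077) and RPL7 (0.88 ± 0.11) were higher at 92 h in 3 of 3 cows, with adjusted p of 0.0670 to 0.0728. PHF11 (0.44 ± 0.075), LOC781304 (0.73 ± 0.098), the folate receptor FOLR2 (0.64 ± 0.12) and FAM19A5 (0.47 ± 0.039) were also on the higher side, and SVOPL (-0.37 ± 0.065) on the lower side. The other probe of PHF11 pointed the other way. ARHGEF18 stood at -0.38 ± 0.00077 and at 0.062 without background correction, with 11 of 18 channel measurements above background at 68 h. None of these passed the test. No list passed, with 2 at an unadjusted p under 0.05 in camera. Proteasome genes came nearest (32 of 45 negative, median -0.19, adjusted p = 0.0677), followed by splicing genes (median -0.15, adjusted p = 0.0739). Adjusted over the list alone, BCAR4 (0.33 ± 0.033), NR5A1 (0.36 ± 0.12), INHBB (0.50 ± 0.23) and the protein kinase A inhibitor PKIB (0.59 ± 0.20) rose and the brighter RPL7 probe (-0.46 ± 0.10) fell. The count of probes was 5486 without cow 2966, 4278 without its 44 h extract alone and 1280 without both extracts (144 with the other values from all arrays). It was 0 without cow 2719 or 2959 (1413 and 1265 at an unadjusted p under 0.05), without the 92 h extract of cow 2719 (2001), with a slide intercept (4743) and within the day of the pair (8197).

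Across the whole period, from 20 h to 92 h, oxidative phosphorylation genes were lower as a group: 65 of 80 were negative, with a median of -0.14 (camera adjusted p = 0.000195, and adjusted p = 0.553 with an estimated correlation). The list median went from 0.029 to -0.19 in cow 2719, whose 92 h extract is 1 of the extracts that stood apart, from 0.017 to -0.16 in cow 2959 and only from 0.042 to -0.011 in cow 2966. Without that extract the adjusted p was 0.0138, and without cow 2719 it was 0.0202. The median of the list over all cows was -0.14 within the day of the pair and -0.13 with a slide intercept. Examples that did not pass by themselves are NDUFAF3, an assembly factor of complex I, at -0.69 ± 0.18, UQCRQ, a subunit of complex III, at -0.34 ± 0.17 and SDHA, a subunit of complex II, at -0.58 ± 0.38. No single probe passed in limma's test, with 1469 at an unadjusted p under 0.05. DGAT2 had the smallest p of the named genes and the largest difference among them, 3.32-fold lower at 92 h (-1.73 ± 0.086, lower in 3 of 3 cows, adjusted p = 0.191). With ACADVL, an enzyme of fatty acid oxidation (-0.38 ± 0.075), it makes up the 2 of 43 lipid and sterol genes that fell adjusted over the list alone (0.000776 for DGAT2). The lipid list did not pass as a group (adjusted p = 0.0739), and SCD, the fatty acid desaturase, stood at -1.26 ± 0.43. The remaining genes by p were AKAP11 (0.58 ± 0.070), TSPAN13 (0.56 ± 0.035), ARL15 (0.70 ± 0.18), ACTR2 (0.69 ± 0.17), IGF2BP3 (0.55 ± 0.18) and OOSP1 (0.41 ± 0.061) on the higher side, and MYH10 (-0.47 ± 0.079), RELN (-0.61 ± 0.18) and RPS14 (-0.59 ± 0.048) on the lower side, with adjusted p from 0.319 to 0.395. RELN and IGF2BP3 each had a further probe that pointed the other way. OOSP1 rose adjusted over the oocyte-specific list alone (0.0218), and the adenylate cyclase ADCY7 fell (-0.82 ± 0.24) adjusted over the list of cAMP and meiotic arrest genes.

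Against 44 h, the 92 h oocytes had lower values of 3 gene groups. Oocyte-specific genes were negative in 29 of 39 (median -0.18, adjusted p = 0.000984), ribosomal protein genes in 52 of 69 (median -0.17, adjusted p = 0.00149) and oxidative phosphorylation genes in 63 of 80 (median -0.20, adjusted p = 0.000175). With an estimated correlation the adjusted p was 0.553 for each of the 3. The oxidative phosphorylation genes fell in cows 2719 (list median from 0.15 at 44 h to -0.19 at 92 h) and 2959 (0.10 to -0.16) but not in cow 2966 (-0.16 to -0.011), and the 92 h extract of cow 2719 is 1 of the extracts that stood apart. In cows 2719, 2959 and 2966 the oocyte-specific median went from 0.21 to -0.20, 0.082 to 0.023 and 0.27 to -0.050. The ribosomal median went from 0.12 to 0.044, 0.057 to 0.029 and 0.18 to -0.10. Over all tested probes the changes of the cows correlated with each other at -0.597 to 0.760 (median -0.589). Adjusted over the list alone, 6 oocyte-specific genes fell, among them ZP4 (-0.76 ± 0.26), ZP3 (-1.05 ± 0.73), ZP2 (-0.63 ± 0.34) and OOSP1 (-0.23 ± 0.014). Likewise RPL21 rose (0.29 ± 0.038), RPS19 (-0.53 ± 0.27), RPLP2 (-0.63 ± 0.094) and COX8B (-0.44 ± 0.16) fell. In the splicing list 3 rose and 4 fell, with SFRS1 higher (0.67 ± 0.076) and PRPF8 lower (-1.02 ± 0.37). PABPC1L (-0.41 ± 0.14) and YBX1 (-0.71 ± 0.33) also fell on that adjustment. So did the antioxidant enzyme GPX4 (-0.63 ± 0.24), the lipid genes DGAT2 (-0.86 ± 0.53), ACACA (-0.32 ± 0.091) and ACADVL (-0.27 ± 0.14), and the DNA repair gene RAD52 (-0.35 ± 0.11). No probe passed over all probes in limma's test, with 2934 at an unadjusted p under 0.05. The smallest p of named genes belonged to RPH3AL (-0.46 ± 0.048), TMED7 (0.62 ± 0.12), SFRS1, IFRD1 (0.60 ± 0.16), ZNF593 (-0.53 ± 0.11), SCAMP3 (-0.85 ± 0.20), RANGRF (-0.51 ± 0.090), SIK3 (-0.39 ± 0.057), DYNLL1 (-0.72 ± 0.23) and QPCT (0.53 ± 0.11), the first at an adjusted p of 0.169. The 2 other probes of SIK3 pointed the other way, and 1 of the 2 other SFRS1 probes had the same direction. The oocyte-specific and ribosomal calls ended without cow 2966 (adjusted p = 0.214 and 0.372) and without its 44 h extract (0.0973 and 0.0792). Without both extracts the oocyte-specific call ended as well (0.123), but not with the other values from all arrays (0.0372). The oxidative phosphorylation call ended without cow 2719 (0.0953). Within the day of the pair the 3 medians were -0.21, -0.18 and -0.24, and with a slide intercept -0.26, -0.17 and -0.22.

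**Figure D2:**
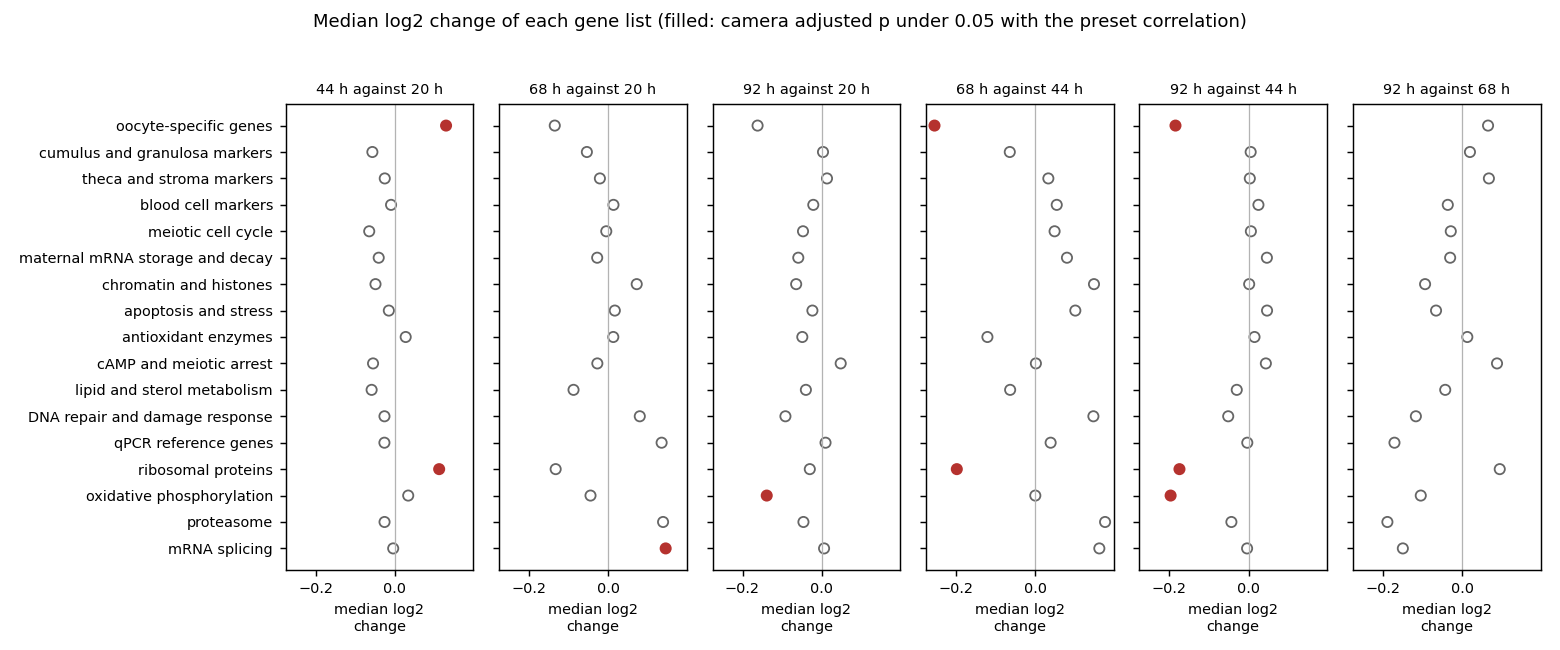
Median log2 change (horizontal axis) of the measured members of 17 gene lists (vertical axis) in the 6 comparisons of coasting times (panels), with a median of 0.13 for the oocyte-specific genes from 20 h to 44 h and -0.25 from 44 h to 68 h. Filled points passed camera with the preset correlation at an adjusted p under 0.05, none passed with an estimated correlation, and with median centring in place of loess the filled points at 44 h against 20 h, 68 h against 20 h and 68 h against 44 h were no longer past the threshold.

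The contrast of the middle times, 44 h and 68 h, with 20 h and 92 h asks for transcripts that rise and fall again over the coasting period. OOSP1 stood first by p, 1.31-fold above the outer times (0.39 ± 0.0077, higher in 3 of 3 cows, adjusted p = 0.106). It was followed by SIK3 (0.30 ± 0.038), CLUL1 (-0.49 ± 0.061), the dynein light chain DYNLL1 (0.51 ± 0.12), LOC100295873 (0.28 ± 0.043), the dim probe of PLAGL1 (-0.34 ± 0.064), ZPBP2 (0.43 ± 0.016), SCAMP3 (0.52 ± 0.21), FKBP1A (0.52 ± 0.14) and CTBP2 (-0.34 ± 0.071). None passed in limma's test, with 2596 probes at an unadjusted p under 0.05. The other probes of ZPBP2, FKBP1A and CTBP2 pointed the other way, and 1 of the 2 other SIK3 probes had the same direction. No list passed in camera, with 3 at an unadjusted p under 0.05, the nearest being the splicing genes (median 0.11, adjusted p = 0.0536). Adjusted over the list alone, OOSP1, the endoplasmic reticulum chaperone HSP90B1 (0.75 ± 0.19) and GPX4 (0.45 ± 0.027) rose, as did SFRS2 (0.43 ± 0.13), SNRPD1 (0.32 ± 0.14) and SNRPC (0.36 ± 0.15) in the splicing list, where SFRS1 fell (-0.36 ± 0.075). The count of probes was 1451 without cow 2966, 646 without its 44 h extract and 739 without both extracts, or 0 with the other values from all arrays (6192 at an unadjusted p under 0.05).

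Over all 4 coasting times together, limma's F test called 0 probes, with 4943 at an unadjusted p under 0.05. The named genes with the smallest p were the dim probe of PLAGL1 (0.19 ± 0.033 at 20 h and -0.53 ± 0.032 at 68 h relative to the mean of the cow), TUBA1D (0.38 ± 0.080 at 44 h and -0.59 ± 0.078 at 68 h) and OOSP1 (-0.40 ± 0.027 at 20 h and 0.27 ± 0.054 at 44 h). They were followed by LYG2, TPRG1L, CLUL1, COQ9, LOC781304, ARHGEF18 and RPH3AL, and the adjusted p of the 10 ran from 0.0542 to 0.0734. The F count was 492 with a dye intercept per slide and 1005 without the 44 h extract of cow 2966, and 154 without both extracts with the other values from all arrays.

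The extracts of a coasting time differed in how alike they were. A profile here is the set of log2 levels relative to the mean of the cow, so a low correlation does not mean that the oocytes expressed different genes. Across the tested probes, which are not independent replicates, the 68 h profiles of the 3 cows correlated at 0.82 to 0.85. The 20 h profiles lay between -0.34 and 0.51, the 44 h profiles between -0.39 and 0.61 and the 92 h profiles between -0.62 and 0.76. The 44 h extract of cow 2966 had 2274 probes over 2-fold from the mean of the cow and the 92 h extract of cow 2719 had 496, against 0 to 24 in the other 10 extracts. A set of 36 control spots whose names begin with DCP moved in the same extracts, at 0.80 and 0.64 log2 units above the mean of the cow, while the negative control spots stood at 0.0069 and 0.025. Cumulus and granulosa markers had medians of -0.0099 (95% bootstrap interval -0.11 to 0.12) and -0.0040 (-0.083 to 0.072) in these extracts. The medians were 0.14 and 0.085 for the 10 theca and stroma markers and 0.048 and 0.065 for the 10 blood cell markers.

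**Figure D3:**
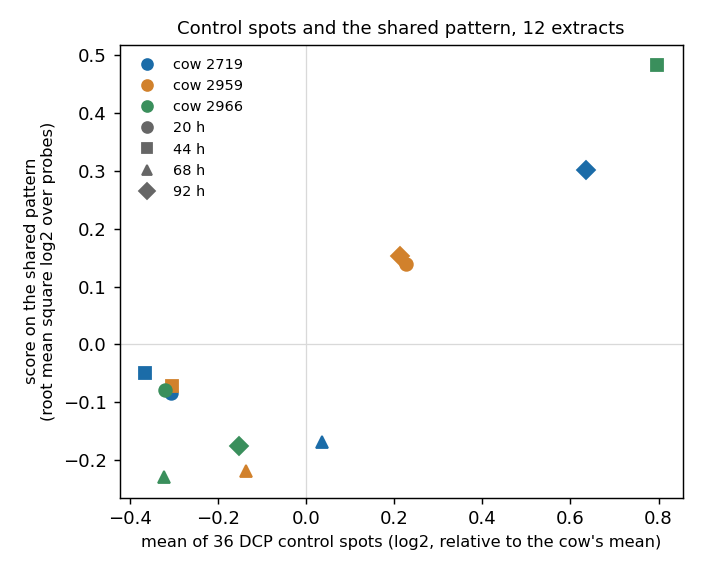
Mean log2 value of 36 DCP control spots (horizontal axis) against the score on the first principal component of the tested probes (vertical axis, root mean square log2 units), for 12 extracts, each relative to the mean of its cow. Colours are cows and symbols coasting times, and the 44 h extract of cow 2966 lies at 0.80 and 0.48 while the 68 h extracts of the 3 cows lie between -0.17 and -0.23 on the vertical axis.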

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

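The tests in this part were chosen after the values were seen. The 36 control spots whose names begin with DCP are outside the comparisons between coasting times, and nothing in the sources used here states what they measure. They stood 0.80 log2 units above the mean of the cow in the 44 h extract of cow 2966 (standard error over the 36 spots 0.057) and 0.64 above it in the 92 h extract of cow 2719 (0.039). The negative control spots were at 0.0069 and 0.025 in these extracts. The 36 spots carry 18 names in 3 sets, and over the 12 extracts the means of the sets correlated with each other at 0.931 to 0.983. The spots are thus not independent, and the standard errors over them do not measure a spread between extracts.

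The same extracts stood apart in the gene probes. One shared pattern, the first principal component of the 12 extract profiles, held 71.7% of the variance of the tested probes, and the second held 9.96%. Its score was 0.48 in the 44 h extract of cow 2966 and 0.30 in the 92 h extract of cow 2719, and the array error of a score was 0.023. The lists with the highest median correlation to this score were theca and stroma markers at 0.43 (8 of 10 positive), ribosomal proteins at 0.34 (41 of 69) and oocyte-specific genes at 0.31 (24 of 39). At the other end were the proteasome at -0.66 (31 of 45 negative), DNA repair and damage response at -0.61 (32 of 46), chromatin and histones at -0.59 (35 of 55) and the qPCR reference genes at -0.55 (9 of 14).

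For this shared pattern the tables argue against coasting time as the whole cause, since 64.02% of its variance lay between extracts of the same coasting time, and the exact within-cow permutation p for coasting time was 0.347 over 576 orders. Cumulus and granulosa cells left on the oocytes, which the labels say were mechanically denuded, cannot be told apart from other sources. The median of 28 markers in these 2 extracts had an upper 95% bootstrap bound of 0.122 at most, but the markers went both ways along the pattern (14 positive, 14 negative) and bright ones such as RGS2 (mean log2 intensity 14.6), STAR (14.4) and FDX1 (14.3) could hide a small share. The amount or the amplification of the RNA of each extract stays open too and may be a cause, as the mean of the DCP spots followed the pattern with a Pearson r of 0.886 (exact within-cow permutation p = 0.0111, 13824 orders) and a Spearman rho of 0.594 (permutation p = 0.0662). That correlation leans on the extracts with high spot values. Without these 2 extracts r was 0.611 (permutation p = 0.178, 864 orders). Over the 8 extracts with the lower spot values, a cut made on the spots themselves, r was -0.532. The 20 h and 92 h extracts of cow 2959 had high spots (0.23 and 0.21) and scores (0.14 and 0.15) as well.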

How the results depend on the processing

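Pairs of coasting times are written here as 68/44 h for 68 h against 44 h, the middle contrast is 44 and 68 h against 20 and 92 h, the 4-time test is the F test, and the 68 h contrast sets 68 h against the mean of the other times. Each probe count below is of probes past an adjusted p of 0.05, to be read beside 16 for 68/20 h, 73 higher and 459 lower for 68/44 h, 1 for 92/68 h, 583 for the 68 h contrast and 0 elsewhere. Numbers of gene lists are to be read beside 2 for 44/20 h, 1 for 68/20 h, 1 for 92/20 h, 2 for 68/44 h, 3 for 92/44 h and 0 elsewhere. Wherever a probe count was 0, limma had 393 to 9707 probes at an unadjusted p under 0.05. The direction of the 9 called gene lists was the same in 21 of 21 settings, and their median, mean and test share 1 sign. The median of all tested probes shifted by at most 0.035 log2 units in any comparison and setting. The log ratios of each array are centred in every setting, so a change common to all probes could not be seen. Of 1819 values of the named genes under the alternatives 1214 had the same direction and the same side of the threshold, 323 had the same direction but no longer passed, and 281 had the same direction and passed only under the alternative. The one with the opposite sign was ARHGEF18 for 92/68 h, at 0.062 without background correction and -0.38 with it. Where a filter left out a gene it has no value there. The direct arrays were used for pairs of times alone, without the middle contrast, the 4-time test, the 68 h contrast and the tests of gene lists. The array as replicate was not run for the 68 h contrast, and gene lists were not tested in that contrast. The cause of the changes below was not tested.

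Among the alternatives set before the data were examined, leaving out background correction gave 51 probes for 68/20 h, 13 for 92/68 h, 11 for the middle contrast and 21 for the 4-time test, with 2 gene lists for 92/20 h, 1 for 92/68 h and 1 for the middle contrast. Median centring gave 75 probes for 68/20 h and 0 for 92/68 h, with 0 gene lists for 44/20 h, 0 for 68/20 h, 5 for 92/20 h, 0 for 68/44 h and 2 for 92/68 h, where 1, 3 and 3 of the lists with 0 were at an unadjusted p under 0.05 in camera. Separate channels after Aquantile normalization with the cow as a block gave 3 probes for 68/20 h, 2 for 92/20 h, 0 for 68/44 h, 0 for 92/68 h and 0 for the 68 h contrast, with 1 gene list for 44/20 h and 1 for the middle contrast. The same channels with no block gave 2 probes for 68/20 h, 0 for 68/44 h, 0 for 92/68 h and 0 for the 68 h contrast, with 1 gene list for 44/20 h and 2 for the middle contrast. Without the filter there were 70 probes for 68/20 h, 874 for 68/44 h, 3 for 92/44 h, 20 for 92/68 h, 9 for the middle contrast and 38 for the 4-time test, and 0 gene lists for 68/20 h (2 at an unadjusted p under 0.05 in camera). The authors' log ratios gave 52 probes for 68/20 h, 325 for 68/44 h (35 higher and 290 lower), 12 for 92/68 h and 13 for the 4-time test.

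Only the directly hybridised arrays, each pair within 1 day, gave 0 probes for 68/20 h, 0 for 68/44 h and 0 for 92/68 h. A dye intercept per slide gave 2 probes for 68/20 h, 4855 for 68/44 h, 0 for 92/68 h, 492 for the 4-time test and 2072 for the 68 h contrast, with 1 gene list for 68/44 h and 1 for the middle contrast. The slide intercept changed no other call, and within the day the other probe counts were 0 as before. Gene lists were not tested within the day, where only their medians were taken, and that of the oocyte-specific genes for 44/20 h was 0.023 there against 0.13. With the array as replicate, which counts each extract several times, there were 3995 probes for 44/20 h, 9840 for 68/20 h, 2551 for 92/20 h, 16508 for 68/44 h, 5122 for 92/44 h, 12580 for 92/68 h, 4838 for the middle contrast and 19244 for the 4-time test, with 1 gene list for 92/68 h and 2 for the middle contrast. An intensity trend with robust variance gave 2 probes for 68/20 h and 1 for 92/44 h. With an estimated correlation camera called 0 gene lists for 44/20 h, 0 for 68/20 h, 0 for 92/20 h, 0 for 68/44 h and 0 for 92/44 h, with 1, 0, 2, 1 and 3 at an unadjusted p under 0.05.

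Leaving out 1 cow at a time gave 0 to 0 probes for 44/20 h, 68/20 h, 92/20 h, 68/44 h, 92/44 h and the 4-time test, 0 to 5486 for 92/68 h, 0 to 1451 for the middle contrast and 0 to 1007 for the 68 h contrast. For gene lists the lowest and highest were 1 and 2 for 44/20 h, 1 and 2 for 68/20 h, 1 and 1 for 92/20 h, 0 and 3 for 68/44 h, 2 and 3 for 92/44 h, 0 and 1 for 92/68 h and 0 and 3 for the middle contrast.

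The remaining alternatives were chosen after the data were seen. Without the 44 h extract of cow 2966 there were 560 probes for 68/20 h, 14 for 68/44 h, 4278 for 92/68 h, 646 for the middle contrast, 1005 for the 4-time test and 3110 for the 68 h contrast, with 4 gene lists for 44/20 h, 2 for 92/68 h and 3 for the middle contrast. Without the 92 h extract of cow 2719 there were 5 for 68/20 h, 0 for 68/44 h, 0 for 92/68 h and 0 for the 68 h contrast. Without both there were 2850 for 68/20 h, 0 for 68/44 h, 1280 for 92/68 h, 739 for the middle contrast and 3434 for the 68 h contrast, with 1 gene list for 92/68 h and 3 for the middle contrast. Without both, with the other extracts' values still taken from all arrays, there were 2503 for 68/20 h, 89 higher and 505 lower for 68/44 h, 144 for 92/68 h, 154 for the 4-time test and 3240 for the 68 h contrast, with 1 gene list for 44/20 h and 3 for the middle contrast. Median spot intensities gave 3 for 92/68 h and 7 for the 4-time test. Brighter probes only (mean log2 intensity above 8.5) gave 0 for 68/20 h, 0 for 68/44 h, 0 for 92/68 h and 0 for the 68 h contrast, and 1 gene list for the middle contrast.

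The mean of the DCP control spots as a covariate gave 5613 probes for 68/20 h, 26 for 92/20 h, 9524 for 68/44 h, 2754 for 92/44 h, 908 for 92/68 h, 407 for the middle contrast, 6898 for the 4-time test and 7788 for the 68 h contrast, with 1 gene list for the middle contrast. Without 2 of the spot names that covariate gave 5567 for 68/20 h, 26 for 92/20 h, 9446 for 68/44 h, 2738 for 92/44 h, 894 for 92/68 h, 392 for the middle contrast, 6832 for the 4-time test and 7648 for the 68 h contrast, with 1 gene list for the middle contrast. The first component of the residuals as a covariate, which comes from the same values it adjusts, gave 3494 for 44/20 h, 8619 for 68/20 h, 1930 for 92/20 h, 13733 for 68/44 h, 2586 for 92/44 h, 10828 for 92/68 h, 3874 for the middle contrast, 13727 for the 4-time test and 13344 for the 68 h contrast, with 2 gene lists for 92/68 h and 2 for the middle contrast.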

Other observations

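The tests of the control spots, of the alike profiles, of the changes in single cows and of the 68 h contrast in this part were chosen after the values were seen. The splits of the extracts for the compared coasting times were set before. With the mean of the DCP spots as a covariate, DGAT2 was lower after 68 h than after 20 h of coasting (-1.52 ± 0.17, standard error, adjusted p = 0.00569) and after 92 h (-1.81 ± 0.18, adjusted p = 0.0423). ARL15 was higher at both times (0.78 ± 0.065, adjusted p = 0.00442, and 0.77 ± 0.070, adjusted p = 0.0358). SFRS1 was higher at 92 h than at 44 h (0.68 ± 0.078, adjusted p = 0.0127), and SMAD6 (0.82 ± 0.054) and CLUL1 (0.76 ± 0.069) were higher at 92 h than at 68 h (adjusted p = 0.0117 for both). OOSP1 passed in the contrast of the middle times (0.39 ± 0.036, adjusted p = 0.0251) and missed at 44 h against 20 h (0.69 ± 0.051, adjusted p = 0.0565). Without the covariate, also with standard errors, DGAT2 stood at -1.52 ± 0.18 (adjusted p = 0.0543) and -1.73 ± 0.18 (0.191), ARL15 at 0.78 ± 0.094 (0.0543) and 0.70 ± 0.094 (0.319) and SFRS1 at 0.67 ± 0.080. In that fit 1 of the 2 other SFRS1 probes had the same direction.

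The gene lists differed in how many members were above background in these oocytes, 39 of 39 for the oocyte-specific genes, 69 of 70 for ribosomal proteins and 76 of 78 for mRNA splicing, against 28 of 36 for cumulus and granulosa markers, 10 of 15 for theca and stroma markers and 10 of 17 for blood cell markers. The median of the oocyte-specific genes relative to the mean of the cow at 68 h was -0.14, -0.19 and -0.076 in cows 2719, 2959 and 2966, and at 44 h 0.21, 0.082 and 0.27. The ribosomal proteins stood at -0.16, -0.15 and -0.086 at 68 h and at 0.12, 0.057 and 0.18 at 44 h.

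The changes from 44 h to 68 h were weighed against 2 technical explanations. The amount or amplification of the RNA stays open. With the DCP spots as a covariate 100% of the called probes were still called in the same direction, but that test could hardly fail. From 44 h to 68 h the spots rose in cows 2719 (-0.37 to 0.036) and 2959 (-0.30 to -0.14). They fell in cow 2966 (0.80 to -0.32), so the covariate took little out of this contrast. The called changes, with the same sign in 3 cows, did not follow the spots, but what these measure is not stated. The 44 h extract of cow 2966 alone stays open. The changes of the other 2 cows correlated at 0.687 over all tested probes, which are not independent replicates (0.486 and 0.614 for the pairs with cow 2966), but 2 cows reached 0.828 in the contrast of the middle times and 0.760 for 92 h against 44 h, where limma called 0 probes (2596 and 2934 at an unadjusted p under 0.05). The count without that extract was 14, and it was 0 without the 92 h extract of cow 2719 and without any 1 cow (4147 to 6953 at an unadjusted p under 0.05 in limma). These lost calls do not decide whether that extract is the cause. The median size of the change was 0.48 without it against 0.51. But the called probes were chosen with that extract in the fit, and 12 of them passed without it. With both extracts left out and the other values taken from all arrays, 292 of the called probes still passed. Those values still draw on the arrays of the extracts left out, and without these arrays 0 of the called probes passed. Not among these explanations was a dye effect that differs between slides, although the dye orientations of this pair sat on different slides, the same in 3 cows. With a dye intercept per slide 529 of the called probes still passed, at a median of 0.67. Open as well is any other difference between the collections of each cow, which the design does not separate from coasting time within a cow, and a biological difference between the times remains a hypothesis that may hold.

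The 68 h extracts were alike across the cows. Of the 64 choices of 1 extract per cow 1 was as alike as the 68 h extracts, namely these themselves, with a mean correlation over the tested probes of 0.835 and 0.717 for the next choice. That next choice was the 92 h extracts of cows 2719 and 2959 and the 44 h extract of cow 2966. They scored 0.30, 0.15 and 0.48 on the shared pattern, while the 68 h extracts scored between -0.17 and -0.23. So the likeness went along with the side of the shared pattern on which the extracts lie. Taking out the part that follows the DCP spots left 0.684 for 68 h. The 44 h extracts then stood first at 0.690, up from 0.017, with 0.378 for 20 h and 0.196 for 92 h. So the likeness was not particular to 68 h once that part was taken out, and no biological explanation of it was tested. This does not decide on the amount or amplification of the RNA as the source of the likeness. The spots differed between the 68 h extracts (0.036, -0.14 and -0.32 in cows 2719, 2959 and 2966), so they could take out little of it, and what they measure is not stated.

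Other splits of the 6 extracts of each pair of coasting times were counted, 10 with the real one, too few for a share under 0.05. At an adjusted p under 0.05 in limma, 1 of 10 splits reached the real count for 68 h against 20 h (16, highest other 0), 1 for 68 h against 44 h (73 higher and 459 lower, highest other 0) and 1 for 92 h against 68 h (1, highest other 0). Where the real count was 0, probes at an unadjusted p under 0.05 were counted, and 3 of 10 splits reached it for 44 h against 20 h (2148, highest other 5488), 2 for 92 h against 20 h (1469, highest other 11209) and 3 for 92 h against 44 h (2934, highest other 13344). Of the 10 splits 4 part the extracts of each cow, and among these the highest other counts were 2065, 1068 and 13344, while the other 6 splits put both extracts of 1 cow on one side and both of another cow on the other. For 92 h against 44 h a split that parts each cow had several times the real count, which points to a structure of the extracts other than coasting time. For 44 h against 20 h and 92 h against 20 h the counts above the real one came from splits that do not part each cow.

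For gene lists past an adjusted p of 0.05, the splits that reached the real number were 3 of 10 for 44 h against 20 h (2 lists, highest other 3), 6 for 68 h against 20 h (1, highest other 2), 6 for 92 h against 20 h (1, highest other 3), 2 for 68 h against 44 h (2, highest other 2) and 2 for 92 h against 44 h (3, highest other 4). Among the 4 splits that part the extracts of each cow, the highest other numbers were 0, 2, 3, 2 and 2, and 1, 2, 3, 2 and 1 splits reached the real number. For 92 h against 68 h, with 2 lists at an unadjusted p under 0.05, 8 of 10 splits had as many (highest other 7), and 3 of the 4 that part each cow (highest other 2). For the contrast of the middle times, 19 of 100 permutations of the coasting times within cows had as many probes at an unadjusted p under 0.05 (2596, highest other 8590) and 66 of 100 as many lists (3, highest other 8), so chance is not excluded there. Nor is it excluded for the F test, with 9 of 100 (4943, highest other 9582). With the DCP spots as a covariate the F test called 6898 probes, which 1 of 100 permutations reached, the real one (highest other 1797). That covariate was chosen after the values were seen, so this count does not exclude a chance order of the times.

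The 68 h extracts against the other 9, fitted as 2 groups, gave 710 probes past an adjusted p of 0.05, and 3 of 64 choices of 1 extract per cow gave as many. That is under 0.05, but the contrast was looked at because the 68 h profiles were alike, and another choice gave 10036, several times the real count, which points to a structure of the extracts. In the fit with all 4 times this contrast gave 67 higher and 516 lower, 22 higher and 529 lower with median centring, and 0 to 1007 without 1 cow.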
